A study of Danio rerio with 24 samples.

How the data were processed

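Total RNA of whole zebrafish embryos of the TL strain was isolated with the miRNeasy kit and its quality assessed on a Bioanalyzer, per the labels' protocols. Each of 4 groups (DMSO or TCDD, 36 or 60 hpf) had 3 biological replicates on each of 2 array types. The Agilent arrays were custom 1-colour (Cy3) 8x15K arrays designed from miRBase 16, and the Exiqon arrays were 2-colour LNA arrays based on miRBase 12, with the sample in Hy3 and a universal reference pool in Hy5, per the labels.

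The Agilent intensity values deposited by the authors come from Feature Extraction 9.5 with the protocol miRNA-v1_95_May07 and a GenePix scanner, per the file headers: the processed signal is a background-subtracted spot intensity, with no scaling between arrays. The deposited value table of these arrays equals the processed signal in every cell (largest difference 0), so it could not change a result. The Exiqon scanner files hold the mean intensity of each spot and of its local background for each channel, from an image analysis program of version 8.0.1, per the file headers. The channel of each file was taken from landmark spots bright only in Hy3 and from the dyes in the labels. The Exiqon value table deposited by the authors is a log2 ratio of sample over reference by its values: it correlated at r = 0.86 to 0.97 with the scanner files' log ratio, with a slope of 1.16 to 1.22, and its array medians were -0.02 to 0.16. How it was normalized is not given in the sources used here. Spot flags (other than intensity, valued as codes) were set by the programs, per the file headers.

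The Agilent files held 490 probes for 231 names that were not marked as controls, and these were read as miRNA probes. No filter on species was applied, so a tested name of another fish, fru-miR-184, is among them. The design text counts more probes, some of other fish, and those outside the 490 were not analysed here. Agilent spots marked as outliers (3.05% to 6.39% per array) were left out. Each spot's processed signal was divided by its array's 75th percentile over the 186 probes detected on all 12 arrays. Those probes were used since on average 49.8% of probes were detected. The log2 values of a probe's spots (5 to 10 per probe) were then averaged. A probe was detected when at least 0.5 of its spots were well above background. Before averaging, scaled spot signals were floored at 0.0273 (log2 -5.19), a level set after the design was fixed. A miRNA was represented by its brightest probe and tested when that probe was detected on all 3 arrays of at least 1 group, which left 134. All 231 miRNAs had several probes; of 113 with several tested probes, the probes' signs differed for 34 at 60 hpf and for 8 between stages, and none passed the threshold in opposite directions. Where a probe was not detected, or was saturated, on every array of a group, the change is given as at least N-fold: the brighter group's mean, with a saturated spot at its value, against the dimmer group's mean, in which each array takes the higher of its lowest detected signal and the probe's own.

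Exiqon spots flagged by the program (4.51% to 15.7% per array) were left out. Background was corrected with normexp (offset 50), each array was normalized by global loess, and the 4 spots of a probe were averaged. Names were held by 255 zebrafish probes (224 names). Of 1960 probes without a name, 1940 were tested apart. A miRNA with several probes took the brightest, a rule set after the design was fixed. A probe counted as detected when its sample channel exceeded the background by 2 background SDs in at least 0.5 of its spots, which tested all but 1 of the names. Exiqon arrays of 36 and 60 hpf correlated between -0.61 and -0.49, while arrays within a group correlated at 0.90 to 0.99. The direction of the ratio was kept because the labels state the dyes, and a pooled reference of both ages would give opposite ratios. On Agilent the correlations were 0.991 to 0.999 within groups and 0.868 to 0.911 across stages. No saturated Exiqon spot was recorded, and 0 to 30 spots per Agilent array were saturated.

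On each platform 1 linear model with 4 group means was fitted over 12 arrays with limma 3.58.1 in R 4.3.3 with the data.table package, version 1.17.8, with TCDD against DMSO at each stage, their mean, their difference (the interaction) and 60 against 36 hpf in DMSO as contrasts. All tests were two-sided, and a change passed at a Benjamini-Hochberg adjusted p under 0.05 within a contrast. An exact permutation test of 3 against 3 arrays cannot give a p below 0.1, so none was used. The platforms were compared over shared names by correlation across miRNAs, in 5 comparisons, without combining p-values. The groups, comparisons, lists and all alternatives not named below as added were chosen before the data were examined.

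The miRNA lists were erythroid, miR-23/miR-24/miR-27 clusters, heart and skeletal muscle, neuronal, miR-430 family, sensory organ, epithelial, liver, gut and pancreas, vascular, cartilage and mesenchyme, leukocyte, let-7 family, miR-17-92 and paralogous clusters, Hox-embedded, stress-associated, and lens and retina. Lists with 3 or more members were tested with camera (preset correlation 0.01, with an estimated correlation as alternative). The erythroid and miR-23/miR-24/miR-27 lists were picked knowing that the study's paper discusses them. The text names, per platform and comparison, up to 10 miRNAs with the highest and 10 with the lowest changes that passed and whose groups did not overlap (12 and 12 between stages), the 5 with the smallest p where fewer than 5 passed, 2 to 4 members of each list with the largest changes, those that passed on both platforms, and the members of the erythroid and miR-23/miR-24/miR-27 lists in the treatment comparisons. From these, the report gives the ones that carry each comparison. The values on one platform of treatment effects that passed on the other, and the probe without a name, were added after their values were seen.

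Replicate 1 of each Agilent group lay on a first slide and replicates 2 and 3 on a second. On Exiqon, 3 TCDD arrays were image-analysed on a later day (replicate 3 of 36 hpf, and replicates 1 and 3 of 60 hpf), and the 3 DMSO arrays of 36 hpf were of a second scan. Alternatives for Agilent were the 75th percentile over all miRNA probes, quantile normalization, normexp background, the deposited value table, no filter on dim probes, the mean of a miRNA's probes, trend and robust variance, only the compared groups, and slide and replicate blocks. Those for Exiqon were no background correction, median centring, quantile normalization of the sample channel alone, the deposited value table, no filter, trend and robust variance, only the compared groups, and day and replicate blocks. Every array was also left out in turn. A lower floor, the second slide only, a filter above the 95th percentile of 28 negative-control spots (196 miRNAs) and the first day only were added after seeing the data.

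The fits were tested on simulated data for the comparison at 60 hpf, with 20 simulations, 8 changed miRNAs per size and a fixed seed of 11. On Agilent, over 134 miRNAs, 58.1% of changes of 0.25 log2, 86.9% of 0.5 and 99.4% of 1 were recovered, with 5.78% false calls. On Exiqon, over the miRNAs tested there, the shares were 81.9%, 99.4% and 100%, with 5.06% false calls. The changed list was found in 100% of simulations and the unchanged list in 0%. The simulated miRNAs varied independently of each other, so these list shares do not test the preset correlation for miRNAs that vary together. Coordinates are those of the array's annotation on danRer5, per the file headers.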

Results

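MicroRNAs (miRNAs) were measured in whole wild-type TL zebrafish embryos after a brief exposure to 2,3,7,8-tetrachlorodibenzo-p-dioxin (TCDD), a ligand of the aryl hydrocarbon receptor that is toxic to fish embryos, or to the solvent DMSO. Exposure began at 30 hours post-fertilization (hpf) and lasted 1 h, and embryos were sampled at 36 and 60 hpf. Each of the 4 groups had 3 biological replicates on custom Agilent arrays and 3 on Exiqon LNA arrays, which gave 12 arrays per platform. The dose of TCDD and whether samples with the same title on the platforms came from the same RNA are not given in the sources used here. On the Agilent arrays 191 to 277 of 490 probes were well above background, and 134 miRNAs were tested. On the Exiqon arrays 248 to 255 of 255 zebrafish probes were above local background, and all but 1 of the 224 names were tested. Changes are given as log2 fold change ± standard error with n = 3 arrays per group, and adjusted p is limma's moderated test after Benjamini-Hochberg adjustment. The number of arrays limits the precision: the median standard error of a treatment effect was 0.0763 log2 on Agilent and 0.0451 on Exiqon.

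The first question was which miRNAs differ 6 h after the start of exposure. At 36 hpf 1 miRNA passed the threshold on each platform and none on both. The groups lay apart, with all 3 arrays of one above all 3 of the other, for 17.2% of miRNAs on Agilent and 25.6% on Exiqon, where chance gives 10%. On Agilent, miR-181a*, the passenger strand of miR-181a, was higher with TCDD. On Exiqon, miR-17a*, a passenger strand of the miR-17-92 cluster, was higher. The miR-23, miR-24, miR-27, miR-144 and miR-451 levels did not differ detectably at this stage.

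On Agilent, 1 of 134 miRNAs passed, upward, with 7 at an unadjusted p under 0.05. MiR-181a* rose by 0.31 ± 0.05 (1.24-fold, adjusted p = 0.0112), and all 3 TCDD arrays lay above all 3 DMSO arrays. Its change was 0.37 on the first slide and 0.29 on the second. The call was lost under 7 alternative settings, and without replicate 2 of the DMSO group (adjusted p = 0.0747) or replicate 1 (adjusted p = 0.0682) or 3 (adjusted p = 0.093) of the TCDD group. On Exiqon the change of miR-181a* was 0.02 ± 0.07 (adjusted p = 0.966). On Exiqon, 1 miRNA passed, upward, with 20 at an unadjusted p under 0.05. MiR-17a* rose by 0.27 ± 0.04 (1.20-fold, adjusted p = 0.00189), with all 3 TCDD arrays above all 3 DMSO arrays. Over the arrays of the first image analysis day its change was 0.25, and on Agilent it was 0.20 ± 0.08 and did not pass (adjusted p = 0.726), but passed without replicate 1 of the 36 hpf DMSO group (0.30, adjusted p = 0.0337). The other miRNAs with the smallest p did not pass: on Agilent miR-338 at 0.19 (adjusted p = 0.337), and miR-30e* at 0.20 and miR-203b at -0.18 (adjusted p = 0.726 for both), and on Exiqon miR-216b at 0.23 (adjusted p = 0.274), and miR-146b at 0.34, miR-21 at -0.12 and miR-218b at -0.10 (adjusted p = 0.413 for each). The 3 DMSO arrays of 36 hpf were scanned in a separate Exiqon scan, so scan and group cannot be told apart in this Exiqon comparison.

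Of the miRNA clusters that carry miR-23, miR-24 and miR-27, the changes at 36 hpf ranged from 0.06 for miR-27c to 0.18 for miR-24 on Agilent and from -0.02 for miR-27a to 0.07 for miR-27b on Exiqon, none past the threshold. As a list they did not pass on either platform (camera adjusted p = 0.114 on Agilent and 0.0617 on Exiqon); with the image analysis day as a block the Exiqon list passed (median 0.06, adjusted p = 0.0111). MiR-451 changed by 0.10 on Agilent and by -0.02 on Exiqon, and miR-144 by 0.06 and -0.05, again without passing. Of the 16 tissue and family lists, no member passed over all miRNAs tested on either platform. The Agilent epithelial list moved down as a set (median -0.07, camera adjusted p = 0.0336, but adjusted p = 0.494 with an estimated correlation), and over the second slide alone its median was -0.01. Adjusted over the list alone, 1 member of the liver, gut and pancreas list rose on Exiqon and 1 member of the stress-associated list fell. Across the miRNAs tested on both platforms, all but 2 of the 134 on Agilent, which are not independent replicates, the changes correlated at r = 0.36 (Spearman's rho = 0.39).

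The second question was whether the profile differs at 60 hpf, 30 h after exposure began. By then the miRNAs of the miR-23/miR-24/miR-27 clusters were higher in TCDD embryos on both platforms. MiR-451, which is abundant in red blood cells, was lower on both platforms. Its cluster partner miR-144 was lower on Exiqon and not detectably different on Agilent. The effects on named miRNAs were small, none reaching 2-fold. The passenger strand miR-17a* was again higher on Exiqon.

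On Agilent, 6 of 134 miRNAs passed the threshold, 5 higher and 1 lower with TCDD, with 13 at an unadjusted p under 0.05. MiR-23a rose by 0.65 ± 0.12 (1.57-fold, adjusted p = 0.0101) and miR-27c by 0.62 ± 0.10 (1.53-fold, adjusted p = 0.00544). MiR-24 rose by 0.55 ± 0.08 (1.46-fold, adjusted p = 0.00498) and miR-23b by 0.24 ± 0.06 (1.18-fold, adjusted p = 0.0456). The liver miRNA miR-122 was higher by 0.57 ± 0.14 (adjusted p = 0.0456), but it was not well above background at 36 hpf and on 1 of the 3 DMSO arrays at 60 hpf, and with normexp background its change was 0.25 (adjusted p = 0.979). At 36 hpf its difference was 0 on both slides, which places it at the floor, so those arrays lower its pooled spread. With only the compared groups it did not pass (adjusted p = 0.329). MiR-451 fell by 0.22 ± 0.05 log2 (adjusted p = 0.021). For each of these 6 all 3 arrays of one group lay apart from all 3 of the other. Of all miRNAs tested on Agilent the groups lay apart for 11.9%, where chance gives 10%. Both slides gave the same direction: on the first and second slide the changes were 0.52 and 0.72 for miR-23a, 0.50 and 0.67 for miR-27c, 0.44 and 0.60 for miR-24, 0.35 and 0.19 for miR-23b, 0.47 and 0.62 for miR-122 and -0.18 and -0.24 for miR-451.

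With the slide as a block, the calls of miR-23b (adjusted p = 0.0725) and miR-122 (adjusted p = 0.0599) ended while their changes stayed as they were. Leaving out 1 array ended the call of miR-122 without replicate 1 (0.53, adjusted p = 0.195) or 3 (0.50, adjusted p = 0.192) of the 60 hpf TCDD group, that of miR-23b without any array but replicate 2 of TCDD (0.21 to 0.27, adjusted p = 0.0736 to 0.195), and that of miR-451 without replicate 1 or 3 of DMSO or replicate 2 or 3 of TCDD (-0.22 to -0.19, adjusted p = 0.0506 to 0.111). Without replicate 3 of TCDD 3 miRNAs passed. Of 18 alternatives, 6 of them with an array left out, all but 1 kept the calls of miR-24 and of miR-27c, and 15 of 18 kept miR-23a, 11 miR-451, 7 miR-122 and 5 miR-23b. The deposited value table is 1 of the 18 and, being equal to the processed signal, could not end a call. MiR-144 changed by 0.06 ± 0.15 on Agilent (adjusted p = 0.951), with a 95% confidence interval from -0.26 to 0.38, and without replicate 2 of the 60 hpf DMSO group, the noisiest array, the change was -0.12.

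**Figure D1:**
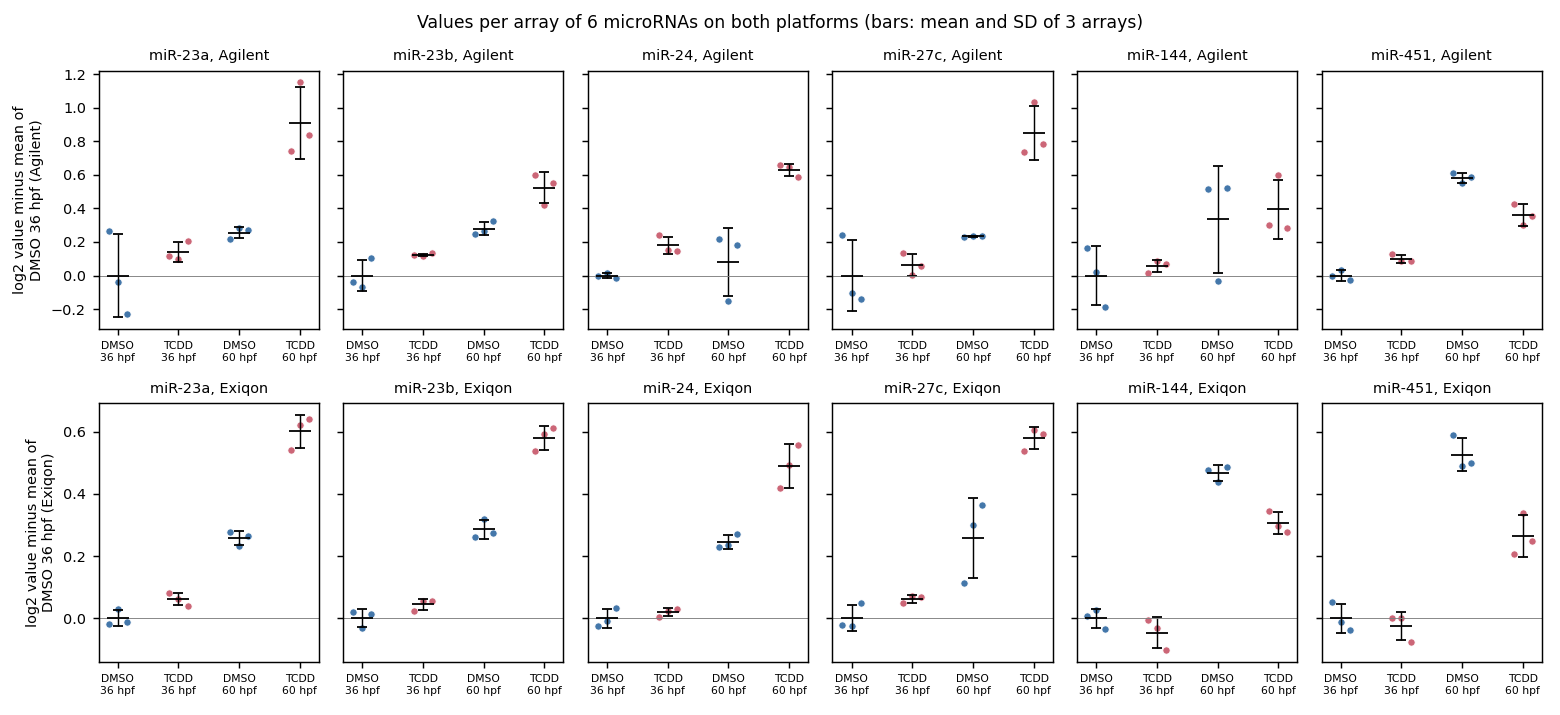
Each point is an array's normalized log2 value of the miRNA minus the mean of the 3 DMSO arrays at 36 hpf, for 6 miRNAs on Agilent (top) and Exiqon (bottom); the bars show the mean and SD of 3 arrays. At 60 hpf the TCDD arrays lie above the DMSO arrays for miR-23a, miR-23b, miR-24 and miR-27c and below them for miR-451 on both platforms, and for miR-144 on Exiqon alone.

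On Exiqon, 14 miRNAs passed and 209 did not. Of the 14, 11 were higher and 3 lower with TCDD, with 56 at an unadjusted p under 0.05. All 8 members of the miR-23/miR-24/miR-27 clusters were among the 11: miR-27e rose by 0.36 ± 0.05 (1.29-fold, adjusted p = 0.000295), miR-23a by 0.34 ± 0.03 (1.27-fold, adjusted p = 6.26e-05), miR-27c by 0.32 ± 0.05 (adjusted p = 0.00178) and miR-23b by 0.29 ± 0.03 (adjusted p = 0.0001). MiR-24 rose by 0.245 ± 0.04 (adjusted p = 0.000856), miR-27b by 0.235 ± 0.03 (adjusted p = 0.000371), miR-27d by 0.19 ± 0.04 (adjusted p = 0.00884) and miR-27a by 0.15 ± 0.04 (adjusted p = 0.0467). The other higher miRNAs were miR-17a* at 0.27 ± 0.04 (adjusted p = 0.000385), miR-338 at 0.175 ± 0.05 (adjusted p = 0.0467) and miR-101a at 0.17 ± 0.04 (adjusted p = 0.00922). MiR-451 fell by 0.26 ± 0.04 log2 (adjusted p = 0.00178), miR-144 by 0.16 ± 0.03 (adjusted p = 0.0129) and miR-19b by 0.12 ± 0.03 (adjusted p = 0.0467). For all 14, all 3 arrays of one group lay apart from all 3 of the other. Of all miRNAs tested on Exiqon the groups lay apart for 22.9%, where chance gives 10%.

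A later image analysis day held 3 TCDD arrays, of which 2 were of 60 hpf. Over the arrays of the first day alone, which left 1 TCDD array at 60 hpf and took the spread from the other groups, the changes were 0.36 for miR-23a, 0.31 for miR-23b, 0.25 for miR-24, 0.35 for miR-27c, 0.34 for miR-27e, 0.24 for miR-27b, 0.22 for miR-27d, 0.15 for miR-27a and 0.22 for miR-17a*. MiR-144 was then at -0.17 (adjusted p = 0.0336) and miR-451 at -0.19 (adjusted p = 0.0737). With the day as a block, fitted over all arrays, 10 miRNAs passed, of which 9 were among the 14. The calls that ended were those of miR-144 (-0.14, adjusted p = 0.084), miR-27a (0.17, adjusted p = 0.0714), miR-101a (0.14, adjusted p = 0.0743), miR-338 (0.13, adjusted p = 0.232) and miR-19b (-0.090, adjusted p = 0.224), and miR-187 passed (-0.32, adjusted p = 0.0102), a miRNA named after its values were seen. Of 17 alternatives, 11 ended the call of miR-27a and 11 that of miR-338. Leaving out 1 array ended that of miR-144 without replicate 3 of the 60 hpf DMSO or TCDD group (-0.15 for both, adjusted p = 0.0583 and 0.0575), that of miR-27a without replicate 2 or 3 of DMSO or replicate 1 of TCDD (highest adjusted p = 0.15), that of miR-19b without these or replicate 3 of TCDD (highest adjusted p = 0.15), and that of miR-338 without replicate 1 or 2 of DMSO or replicate 1 or 3 of TCDD (highest adjusted p = 0.144). Without replicate 2 of the 60 hpf TCDD group, 48 miRNAs passed, 22 higher and 26 lower; the 60 hpf TCDD arrays were then all of the later day and the DMSO arrays all of the first, so treatment and day cannot be told apart in that fit. With median centring of each array in place of loess no Exiqon miRNA passed in any treatment comparison: the change of miR-23a was 0.34 and that of miR-451 -0.24, but the median standard error rose to 0.105.

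**Figure D2:**
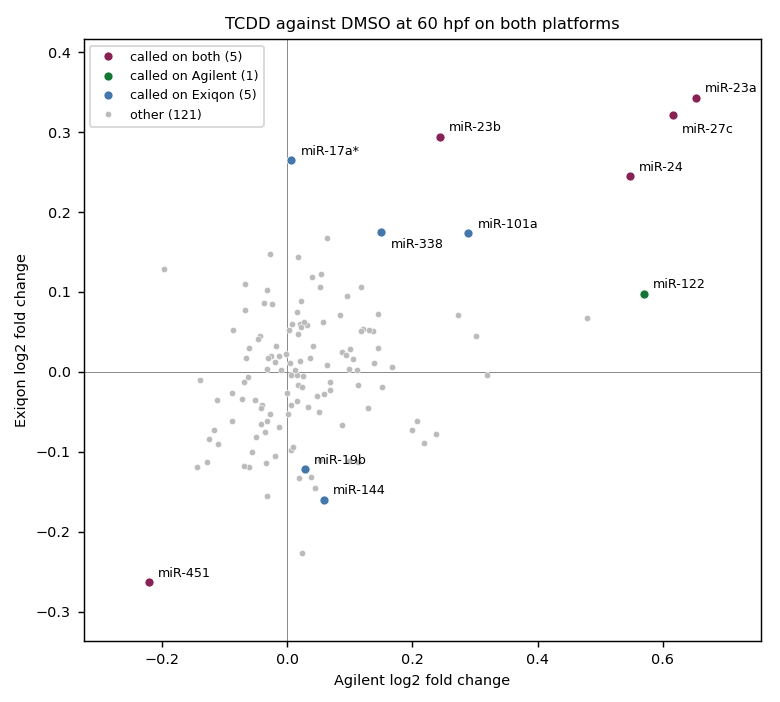
Log2 fold change of TCDD against DMSO at 60 hpf on Agilent (x axis) and Exiqon (y axis) for the miRNAs tested on both, with 3 arrays per group and platform; colours show the platforms on which adjusted p was under 0.05. MiR-23a, miR-23b, miR-24 and miR-27c lie at the upper right and miR-451 at the lower left.

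As a list, the miR-23/miR-24/miR-27 clusters rose at 60 hpf on both platforms. The Agilent array also carries probes of miR-27a, miR-27b, miR-27d and miR-27e. These were not detected on all 3 arrays of any group, so they were not tested there. Over all miRNAs tested, 4 of 4 measured members rose on Agilent (camera adjusted p = 1.6e-08, and adjusted p = 0.00225 with an estimated correlation) and 8 of 8 on Exiqon (camera adjusted p = 6.69e-12, and adjusted p = 0.00603 with an estimated correlation), and adjusted over the list alone the counts were also 4 and 8. The list's median was 0.58 on Agilent and 0.64 over its second slide. On Exiqon it was 0.27, also with the day as a block, and 0.28 over the first image analysis day. The slide block could not change the Agilent median, since every group was divided over the slides alike. The erythroid list, miR-451 and miR-144, was too short for camera; 1 of its members fell on Agilent and 2 fell on Exiqon over all miRNAs tested. Both lists were picked knowing that the study's paper discusses these miRNAs, so they are not independent evidence. On the danRer5 build of the array's annotation, miR-451 lies at chromosome 5, 41283987 to 41284007, and miR-144 at 41284130 to 41284148. MiR-23b lies at chromosome 10, 10612701 to 10612715, and a copy of miR-24 at 10618952 to 10618969; the miR-24 probe also matches chromosomes 3, 8 and 22.

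Other lists moved little at 60 hpf. The liver, gut and pancreas list rose on Agilent (median 0.20, camera adjusted p = 0.0111, but adjusted p = 0.185 with an estimated correlation) with 1 of 5 members passing, and 0 of 7 passed on Exiqon, where miR-122 was at 0.10 ± 0.04 (adjusted p = 0.182). On Exiqon the miR-17-92 and paralogous clusters fell as a set (median -0.06, camera adjusted p = 0.0149, but adjusted p = 0.381 with an estimated correlation), with 1 of 15 members lower over all miRNAs tested and 4 adjusted over the list alone; on Agilent 0 of 14 passed. Adjusted over the list alone, 1 of 4 vascular members rose on Agilent, and on Exiqon 2 of 7 epithelial members fell and, of 5 lens and retina members, 2 rose and 1 fell. In the muscle, neuronal, miR-430, sensory organ, cartilage, leukocyte, let-7, Hox-embedded and stress-associated lists, no member passed on either platform by limma, over all miRNAs or over the list alone.

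The platforms gave the same sign for all 6 miRNAs that passed on Agilent. Of those that passed on Exiqon and were tested on both, 8 had the same sign, miR-144 did not, and miR-19b was saturated on Agilent on 5 of the 6 arrays of 60 hpf, so its sign there was not compared. The 5 that passed on both, in the same direction, were miR-23a, miR-23b, miR-24, miR-27c and miR-451. On Agilent miR-17a* was at 0.01 ± 0.08 at 60 hpf, miR-101a at 0.29 ± 0.22 and miR-338 at 0.15 ± 0.06, none past the threshold; the probe of miR-19b saturated on no array was at -0.078. Across the shared miRNAs r was 0.48 and Spearman's rho 0.30, and with no filter on dim probes r was 0.30.

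Averaged over both stages, the miR-23/miR-24/miR-27 clusters were higher with TCDD on both platforms, though no single member passed at 36 hpf. On Agilent 5 miRNAs passed, all higher: miR-23a at 0.40 ± 0.09 (adjusted p = 0.0333), miR-24 at 0.36 ± 0.06 (adjusted p = 0.00871), miR-27c at 0.34 ± 0.07 (adjusted p = 0.0333), and miR-23b at 0.18 ± 0.04 and miR-338 at 0.17 ± 0.04 (adjusted p = 0.0342 for both). With the slide as a block only miR-24 (adjusted p = 0.00834) and miR-27c (adjusted p = 0.0485) passed; miR-23a (adjusted p = 0.0511), miR-23b (adjusted p = 0.0589) and miR-338 (adjusted p = 0.0555) did not, with the same changes. With an array left out 1 miRNA passed, save for 3 without replicate 1 or 3 of 36 hpf DMSO or replicate 1 of 60 hpf TCDD and 5 without replicate 2 of 60 hpf TCDD. Of 23 alternatives, arrays left out included, 2 ended the call of miR-24, 12 that of miR-27c, 14 that of miR-23a and 17 each those of miR-23b and miR-338. On Exiqon, where the 36 hpf DMSO arrays of this comparison were of the second scan, 9 were higher and 5 lower. The higher ones were miR-17a* at 0.27 ± 0.03 (adjusted p = 5.09e-05), miR-23a at 0.20, miR-23b at 0.17, miR-24 at 0.13, miR-27b at 0.15, miR-27c at 0.19, miR-27d at 0.10, miR-27e at 0.21 and miR-184 at 0.14, with the highest adjusted p of 0.0358 for miR-27d and miR-184. MiR-203b at -0.15 and miR-20b at -0.11 (adjusted p = 0.0348 for both), miR-451 at -0.14 (adjusted p = 0.0162), and miR-144 and miR-92b at -0.10 (adjusted p = 0.0303 for both) were the lower ones; the fall of miR-203b turned to 0.06 in the sample channel alone. With the day as a block none of these 5 passed (lowest adjusted p = 0.179, for miR-451 at -0.097), and neither did miR-184 (0.085, adjusted p = 0.355); the other 8 higher ones passed, as did miR-187 (-0.22, adjusted p = 0.0169). The Exiqon count was 25 without replicate 2 of 60 hpf TCDD, 7 without replicate 1 and 8 without replicate 2 of 36 hpf DMSO, 8 without replicate 2 of 36 hpf TCDD, and 9 without replicate 1 or 3 of 36 hpf TCDD or replicate 3 of 60 hpf DMSO. MiR-451 was at -0.06 and miR-144 at 0.06 on Agilent, where neither passed, and miR-27a at 0.06 on Exiqon did not pass (adjusted p = 0.222).

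The miR-23/miR-24/miR-27 list held 4 of 4 higher members on Agilent (camera adjusted p = 2.02e-09, and adjusted p = 0.00149 with an estimated correlation) and 7 of 8 on Exiqon (camera adjusted p = 2.87e-11, and adjusted p = 0.00742 with an estimated correlation), with 8 adjusted over the list alone. The Exiqon miR-17-92 list again moved down (camera adjusted p = 0.0135, but adjusted p = 0.368 with an estimated correlation), with 2 of 15 members lower. On Exiqon both erythroid members and 1 epithelial member were lower and 1 lens and retina member higher; no member of another list passed over all miRNAs tested. Adjusted over the list alone, 1 more epithelial, 1 muscle and 1 lens and retina member were lower and 1 liver, gut and pancreas member higher on Exiqon. Across shared miRNAs r was 0.56 and Spearman's rho 0.45 (r = 0.37 with no filter on dim probes), and 4 miRNAs passed on both platforms.

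Whether the effect of TCDD differed between the stages was tested as an interaction. As a set, the miR-23/miR-24/miR-27 clusters responded more at 60 than at 36 hpf on both platforms (camera adjusted p = 0.00128 on Agilent, median difference 0.44, and adjusted p = 0.0485 with an estimated correlation; camera adjusted p = 1.5e-09 on Exiqon, median difference 0.24, and adjusted p = 0.0136 with an estimated correlation). On Exiqon miR-27e (0.30 ± 0.06, adjusted p = 0.0396), miR-23a (0.28 ± 0.05, adjusted p = 0.0152) and miR-23b (0.25 ± 0.05, adjusted p = 0.0152) passed singly, and 8 of 8 members adjusted over the list alone. The 36 hpf DMSO group alone was of the second Exiqon scan, so scan and interaction cannot be told apart there. On Agilent 0 of 4 members passed over all miRNAs and 3 over the list alone, with miR-27c at 0.55 (adjusted p = 0.124), miR-23a at 0.51 (adjusted p = 0.341) and miR-24 at 0.37 (adjusted p = 0.315). On Agilent 2 miRNAs passed, both with a more negative effect at 60 hpf: miR-181a* at -0.38 ± 0.07 and miR-451 at -0.32 ± 0.07 (adjusted p = 0.0347 for both). With 1 array left out, both calls held only without replicate 1 of 60 hpf TCDD. Without replicate 3 of 36 hpf DMSO that of miR-451 ended (-0.305, adjusted p = 0.0772), and without any one of the other 10 arrays both ended (adjusted p = 0.0543 to 0.155). Of 23 alternatives, arrays left out included, 17 ended the call of miR-181a* and 15 that of miR-451. The 3 Exiqon calls became 13 without replicate 2 and 6 without replicate 1 of 60 hpf TCDD, 1 without replicate 1 of 36 hpf DMSO, 36 hpf TCDD or 60 hpf DMSO, and 0 by limma without replicate 3 of 36 hpf DMSO, with 27 at an unadjusted p under 0.05. On Exiqon the interaction of miR-451 was -0.24 ± 0.06 and did not pass, and that of miR-181a* was 0.09 ± 0.09. The Agilent liver, gut and pancreas list differed between stages (camera adjusted p = 0.0358, but adjusted p = 0.304 with an estimated correlation). Adjusted over the list alone, both erythroid members and 2 leukocyte members had a more negative effect at 60 hpf on Exiqon, and 1 leukocyte and 1 stress-associated member a more positive one. Across shared miRNAs the interactions correlated at r = 0.30 (Spearman's rho = 0.25).

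Embryonic age, compared in the DMSO groups, changed far more miRNAs than TCDD did. Between 36 and 60 hpf let-7a, let-7c, let-7d, let-7g, the miR-125 members and the brain miRNAs miR-9 and miR-124 rose, as did the sensory organ miRNAs miR-96, miR-182 and miR-183. The maternal-to-zygotic miR-430 family fell, on Agilent 4.17-fold to 4.96-fold for its 3 members without saturation. The cartilage and mesenchyme miRNAs miR-140, miR-199 and miR-214 and the gut and liver miRNAs miR-192 and miR-122 rose, while the epithelial miR-203 pair fell. The erythroid miR-451 rose.

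On Agilent 105 of 134 miRNAs passed, 61 higher and 44 lower at 60 hpf, and the groups lay apart for 77.6%, where chance gives 10%. On Exiqon 108 were higher and 37 lower and 78 did not pass, and the groups lay apart for 74.4%. With the 75th percentile taken over all miRNA probes the share of higher calls on Agilent fell from 58.1% to 40.5%, and the median of all miRNAs from 0.10 to -0.18 log2, and with quantile normalization to 42.7% and -0.12. On Exiqon median centring moved the share from 74.5% to 92.4% and the median from 0.12 to 0.32, and the sample channel alone moved the share to 62.1%. Changes smaller than these shifts have no settled direction. Across the shared miRNAs the platforms correlated at r = 0.87 (Spearman's rho = 0.88), and of 85 miRNAs that passed on both 80 had the same sign, 54 higher and 26 lower. On Exiqon all 36 hpf DMSO arrays were of the separate scan. In a comparison chosen after the results were seen, between the TCDD groups, whose Exiqon arrays were all of 1 scan, the stage changes correlated with those in DMSO at r = 0.98 across miRNAs, and every miRNA that passed in both had the same sign, so the scan does not account for those.

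Among the largest rises, let-7a rose by 2.96 ± 0.12 on Agilent (7.76-fold, adjusted p = 3.94e-10) and 1.96 ± 0.04 on Exiqon (3.89-fold, adjusted p = 1.64e-13), and miR-9* by 2.58 ± 0.07 (5.97-fold) and 2.33 ± 0.04 (5.01-fold). MiR-9 itself was saturated on all 3 Agilent arrays of 60 hpf DMSO and rose at least 4.24-fold there and 5.60-fold on Exiqon. MiR-125a was not well above background on Agilent at 36 hpf and rose at least 4.90-fold, and by 1.90 log2 on Exiqon. Let-7g rose by 2.16 and 1.61 log2, miR-124 by 1.61 and 1.64, miR-138 by 1.64 and 1.41, miR-125b by 1.94 and 1.48 and miR-181a* by 2.69 and 1.22. The platforms disagreed on 2 of the largest Agilent rises: let-7f rose by 2.97 on Agilent and changed by 0.17 on Exiqon (adjusted p = 0.163), and miR-129* rose by 2.46 and changed by 0.13 (adjusted p = 0.195). All 3 arrays of 60 hpf lay above all 3 of 36 hpf on both platforms for each of these miRNAs. Some Agilent probes of 1 miRNA differed in size: 1.14 and 2.97 log2 for let-7f, 0.42 and 1.64 for miR-138 and 0.72 and 2.35 for miR-125a. Over the 113 miRNAs with several tested probes the median gap was 0.07 and the largest, that of let-7f, 1.83.

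**Figure D3:**
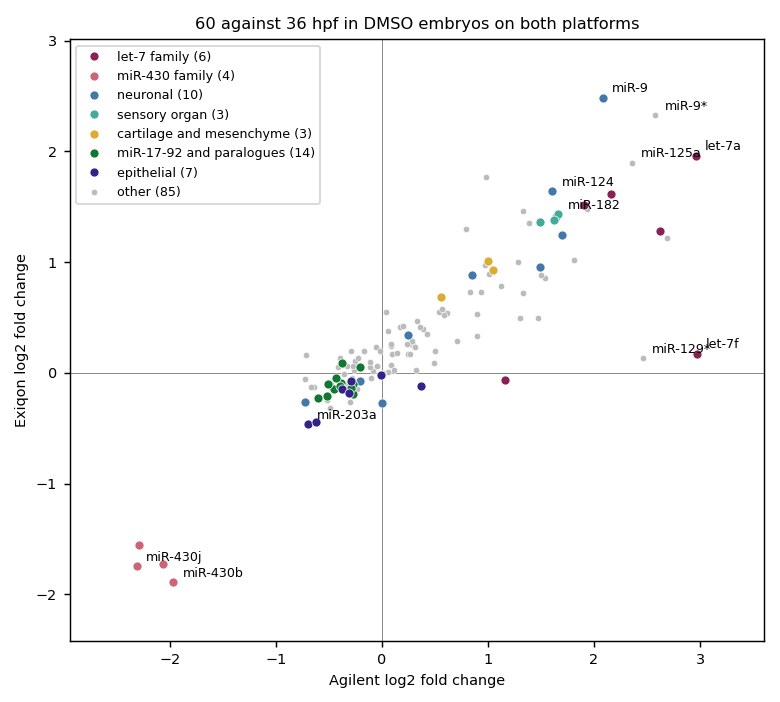
Log2 fold change of 60 against 36 hpf in DMSO embryos on Agilent (x axis) and Exiqon (y axis) for the miRNAs tested on both, coloured by miRNA list, with 3 arrays per group and platform. The miR-430 family lies at the lower left, and the neuronal and sensory organ miRNAs and let-7a at the upper right.

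The falls were led by the miR-430 family. On Agilent miR-430j fell by 2.31 ± 0.05 log2 (adjusted p = 2.97e-12), miR-430c by 2.29 ± 0.13 and miR-430a by 2.06 ± 0.07. The tested probe of miR-430b was saturated on 2 of the 3 DMSO arrays of 36 hpf, so its fall of 1.97 log2 is a lower bound; its other probe, saturated on none, fell by 2.34 ± 0.07. On Exiqon miR-430b fell by 1.89 ± 0.06 (adjusted p = 7.3e-12), miR-430j by 1.75 ± 0.05, miR-430a by 1.73 ± 0.06, miR-430c by 1.55 ± 0.05 and miR-430i by 1.21. The list fell on Agilent for 4 of 4 members (camera adjusted p = 0.00104, but adjusted p = 0.28 with an estimated correlation) and on Exiqon for 5 of 5 (camera adjusted p = 1.08e-06, and adjusted p = 0.0281 with an estimated correlation). These falls kept their direction under every scaling. MiR-203a fell by 0.69 and 0.46, and miR-203b by 0.62 and 0.45, in all 3 arrays against all 3.

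Of the let-7 list 6 of 6 members rose on Agilent (camera adjusted p = 0.0259, but adjusted p = 0.28 with an estimated correlation) and 8 of 10 on Exiqon. The neuronal list held 7 higher and 2 lower of 10 on Agilent and 10 higher and 2 lower of 16 on Exiqon. All 3 sensory organ members rose on both platforms, by 1.49 to 1.66 on Agilent and 1.37 to 1.43 on Exiqon. Of the cartilage and mesenchyme list 3 of 3 and 4 of 4 rose, with miR-199 at 0.995 and 1.01 and miR-214 at 1.05 and 0.93. Of the liver, gut and pancreas list 5 of 5 and 6 of 7 rose, with miR-192 at 1.33 and 0.72 and miR-122 at least 2.34-fold higher on Agilent, where 2 of 3 arrays of 60 hpf measured it, and 1.00 log2 higher on Exiqon. As sets, neither of these 2 lists passed (camera adjusted p = 0.118 and 0.0725 for cartilage and mesenchyme and 0.106 and 0.0804 for liver, gut and pancreas). The lens and retina list held 3 of 4 and 4 of 5 higher members, among them miR-181c at 1.38 and 1.35 and miR-204 at 0.56 and 0.58. MiR-451 rose by 0.58 ± 0.05 (adjusted p = 2.81e-07) and 0.53 ± 0.04 (adjusted p = 2.05e-07), and miR-144 by 0.47 ± 0.03 on Exiqon (adjusted p = 6.56e-08), while 0.335 ± 0.15 on Agilent missed the threshold (adjusted p = 0.0529).

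The remaining lists were mixed. The miR-17-92 and paralogous clusters held 13 lower of 14 on Agilent (camera adjusted p = 8.84e-05, but adjusted p = 0.17 with an estimated correlation) and 9 lower and 1 higher of 15 on Exiqon (camera adjusted p = 0.000248, but adjusted p = 0.0723 with an estimated correlation), where median centring turned members such as miR-17a from -0.19 to 0.24. The epithelial list held 2 higher and 5 lower of 8 on Agilent and 6 lower of 7 on Exiqon (camera adjusted p = 0.00115, but adjusted p = 0.0723 with an estimated correlation), where median centring turned miR-200b from -0.07 to 0.34. Of the miR-23/miR-24/miR-27 list 1 of 4 members rose on Agilent and 8 of 8 on Exiqon; on Agilent miR-24 moved from 0.08 to -0.40 with quantile normalization. The muscle list held 2 higher and 2 lower of 6 on each platform, with miR-133a at 0.50 and 0.20 and miR-206 at -0.30 and -0.26; in the sample channel alone miR-133a turned to -0.31, quantile normalization turned miR-206 to 0.09 on Agilent and median centring to 0.16 on Exiqon. The vascular list held 1 higher and 2 lower of 4 and 2 higher and 1 lower of 5, with miR-143 at 0.79 and 1.30. The Hox-embedded list held 1 higher and 4 lower of 6 and 1 higher and 1 lower of 6. The leukocyte list held 0 higher and 1 lower of 2 and 2 higher and 1 lower of 8, and miR-142a-3p was at -0.29 on Agilent and 0.20 on Exiqon. The stress-associated list held 1 higher and 2 lower of 3 and 4 higher of 5, with miR-34 at 0.90 and 0.54 and miR-210 at -0.17 and 0.20. All these counts are over all miRNAs tested. Adjusted over the list alone the stage counts were the same, except for 11 higher neuronal and 1 higher and 0 lower leukocyte members on Exiqon and 2 higher erythroid members on Agilent.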

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

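The tests of the image analysis day for the miR-23/miR-24/miR-27 members, for miR-451 and for miR-144, of hybridisation between related miRNAs, of the red blood cell share and of miR-17a* were chosen after the results were seen, and so was the fit of unnamed probes; the splits of samples and the test of developmental delay were chosen before.

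The effect of TCDD differed between stages for 5 miRNAs, by the interaction test. On Agilent miR-181a* was at -0.38 and miR-451 at -0.32, both more negative at 60 hpf. On Exiqon miR-23a was at 0.28, miR-23b at 0.25 and miR-27e at 0.30, all more positive at 60 hpf. The 36 hpf DMSO arrays alone were of the second Exiqon scan, so scan and interaction cannot be told apart there. These counts were set against other splits of the samples: of 100 splits on Agilent, the real one included, 4 gave as many as the real 2, and the highest other gave 5. The splits exchanged treatment labels within a stage, so they stand for no effect of TCDD at either stage, not for equal effects. The share therefore does not decide on chance for an interaction. The splits did not keep the slides together. With the slide as a block both calls passed (adjusted p = 0.044 for both), and with the replicate block neither did (adjusted p = 0.0573 for both). On Exiqon 12 of 100 splits gave as many as the real 3, with 14 the highest other. For the same reason this share does not decide either, and chance is not excluded there. The highest other split on each platform exchanged DMSO and TCDD labels at 60 hpf, which turns the interaction into the treatment effect itself. The single interactions rest on few arrays. On Agilent only leaving out replicate 1 of 60 hpf TCDD left both calls. Without replicate 3 of 36 hpf DMSO that of miR-451 ended (-0.305, adjusted p = 0.0772), and without any one of the other 10 arrays both ended, with miR-181a* at -0.40 to -0.35 (adjusted p = 0.0543 to 0.143) and miR-451 at -0.34 to -0.29 (adjusted p = 0.0543 to 0.155). Of 23 alternatives, arrays left out included, 17 ended the call of miR-181a* and 15 that of miR-451. On Exiqon 14 of 22 ended that of miR-27e, 6 that of miR-23b and 3 that of miR-23a. That of miR-23a ended without replicate 3 of 36 hpf DMSO (0.29, adjusted p = 0.05), and that of miR-23b without replicate 1 (0.24, adjusted p = 0.0689) or 3 (0.24, adjusted p = 0.0704) of 36 hpf DMSO, replicate 1 of 36 hpf TCDD (0.24, adjusted p = 0.0665) or replicate 1 of 60 hpf DMSO (0.24, adjusted p = 0.0535). That of miR-27e held without replicate 2 of 36 hpf TCDD, replicate 3 of 60 hpf DMSO or replicate 1 or 2 of 60 hpf TCDD, and ended without any one of the other 8 (0.265 to 0.32, adjusted p = 0.0637 to 0.11).

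The first pattern is the rise of the miR-23/miR-24/miR-27 members at 60 hpf. The later image analysis day is argued against for miR-23a, miR-23b, miR-24 and miR-27c, since all 4 passed upward on Agilent, which has no such day, and for miR-27b, miR-27d and miR-27e, since all 3 passed with the day as a block over all arrays, which takes the day's shift as equal at both stages. For miR-27a the day stays open: with the block its change went from 0.15 ± 0.04 to 0.17 ± 0.05 and its call ended (adjusted p = 0.0714), as its standard error grew. On Agilent, hybridisation between the subfamilies is argued against by probe sequences that share at most 7 consecutive bases. Exiqon probe sequences were not compared. Hybridisation between the subfamilies therefore stays open for miR-27a, miR-27b, miR-27d and miR-27e, which passed on Exiqon alone. Within a subfamily Agilent probes share up to 14 bases, so which of the miR-27 members, or of the miR-23 pair, changed stays open. An effect of TCDD may therefore raise at least 1 member of each subfamily, a hypothesis found and tested on the same data.

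The second pattern is the fall of miR-451 and, on Exiqon, miR-144 at 60 hpf. The day is argued against for miR-451 by the Agilent change of -0.22. For miR-144 it stays open: with the day as a block its change went from -0.16 ± 0.03 to -0.14 ± 0.04 and its call ended (adjusted p = 0.084), with a smaller change and a larger standard error. Over the first day it was at -0.17 (adjusted p = 0.0336), but with 1 TCDD array at 60 hpf, which excludes nothing, and Agilent does not decide, at 0.06 ± 0.15. Developmental delay would move other miRNAs back along their stage change by the share that miR-451 lost, -0.42 ± 0.09 of its Exiqon stage change, but over 130 other miRNAs the slope of the Agilent treatment change on the Exiqon stage change was 0.028 ± 0.017, and with platforms exchanged 0.0078 ± 0.0084 against -0.45 ± 0.08. A lower share of red blood cell RNA stays open: the changes of miR-451 and miR-144 differed by -0.10 ± 0.05 on Exiqon and -0.28 ± 0.17 on Agilent. An effect of TCDD on red blood cells or on these miRNAs was not tested otherwise.

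The third pattern is the rise of miR-17a* on Exiqon at both stages. As the only cause, the later day is argued against by 0.25 at 36 hpf over the first day. The second scan as the only cause is argued against by 0.27 at 60 hpf, where every array was of the first scan. Each value leaves the other artifact in place: the 36 hpf DMSO arrays were of the second scan, and 60 hpf TCDD replicates 1 and 3 of the later day. With the day as a block the 60 hpf change was 0.22 ± 0.04 (limma adjusted p = 0.00363). That fit takes the day's shift as equal at both stages. Over 6 guide strands of the cluster the median was -0.022 (SD 0.026), against 0.27 for miR-17a* over both stages. This argues against a shared rise of the mature guide strands. The cluster transcript was not measured, so a rise of it stays open. On Agilent miR-17a* was at 0.20 at 36 hpf, where it passed only without replicate 1 of 36 hpf DMSO (0.30, adjusted p = 0.0337), and at 0.01 at 60 hpf, so hybridisation of another RNA to the Exiqon probe stays open and was not tested.

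Among 1940 Exiqon probes without a miRNA name that were tested apart, 1 passed at 36 hpf and 1 at 60 hpf, with 63 and 268 at an unadjusted p under 0.05 by limma. It was the same probe, 28351, which no comparison of the named miRNAs used. It was 2.26 ± 0.08 log2 higher with TCDD at 36 hpf (4.79-fold, adjusted p = 2.04e-09) and 1.29 ± 0.08 higher at 60 hpf (2.45-fold, adjusted p = 1.65e-06). Its ratio was -1.29 ± 0.04 (SD, n = 3) in DMSO and 0.97 ± 0.12 in TCDD embryos at 36 hpf, and -1.33 ± 0.13 and -0.03 ± 0.09 at 60 hpf. The effect was smaller at 60 hpf (interaction -0.96 ± 0.11, adjusted p = 0.00243). The files give no target for this probe, and no explanation was tested.

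The counts were also set against other splits of the samples. For the comparisons of 3 against 3 arrays the 10 splits are too few for a share under 0.05: on Agilent the real split gave 1 call at 36 hpf (highest other 0), 6 at 60 hpf (highest other 1) and 105 between stages (highest other 0), and on Exiqon 1 (highest other 0), 14 (highest other 0) and 108 higher and 37 lower (highest other 0). In each of these 1 split, the real one, gave as many. For the effect over both stages 1 of 100 drawn splits, the real one, gave as many calls on each platform, with 5 against 3 on Agilent and 14 against 9 on Exiqon. This argues against chance only for the counts fitted without a block. The splits kept neither the slides nor the image analysis day together: 2 miRNAs passed with the slide as a block, both among the 5, and 9 with the day as a block, of which 8 were among the 14. With the replicate block 1 miRNA passed on Agilent, while the Exiqon count did not fall. With 1 array left out the Agilent count was 3 without replicate 1 or 3 of 36 hpf DMSO or replicate 1 of 60 hpf TCDD, 5 without replicate 2 of 60 hpf TCDD and 1 without any other. The Exiqon count was 7 without replicate 1 of 36 hpf DMSO, 8 without replicate 2 of 36 hpf DMSO or TCDD, 9 without replicate 1 or 3 of 36 hpf TCDD or replicate 3 of 60 hpf DMSO, and 25 without replicate 2 of 60 hpf TCDD.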

How the results depend on the processing

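The tests with a lower Agilent floor, over the second slide only, above the Exiqon negative controls and over the first image analysis day only were chosen after seeing the data; the others were planned. For single miRNAs and lists, 3053 comparisons with an alternative kept direction and side of the threshold, 245 kept the direction and lost the call, 13 gained it and 86 changed sign; for counts of calls and correlations, 81 stayed within 1.5 times or within their spread and 45 moved. Where no cause is named, the cause was not tested. The deposited Agilent value table, equal to the processed signal, counts among the alternatives and could not change a result.

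The rises of miR-23a, miR-23b, miR-24 and miR-27c at 60 hpf and the fall of miR-451 kept their direction under every setting on both platforms. On Agilent the call of miR-24 ended with only the compared groups (adjusted p = 0.0557) and that of miR-27c with normexp background (0.32, adjusted p = 0.703). That of miR-23a ended with quantile normalization (adjusted p = 0.0551), normexp background (adjusted p = 0.147) and no filter on dim probes (adjusted p = 0.0607), and that of miR-451 with the 75th percentile over all miRNA probes (adjusted p = 0.144), only the compared groups (adjusted p = 0.209) and the second slide only (adjusted p = 0.146). Those of miR-23b and miR-122 ended under 8 and 9 settings (highest adjusted p = 0.48 and 0.979). On Exiqon median centring ended every call. Besides it, no setting ended those of miR-23a, miR-23b, miR-27c and miR-27e. The sample channel alone ended 10: those of miR-24 and miR-27d (adjusted p = 0.0847 for both), miR-27b (adjusted p = 0.0924), miR-27a (adjusted p = 0.142), miR-17a* (adjusted p = 0.0696), miR-101a (adjusted p = 0.88), miR-338 (adjusted p = 0.825), miR-144 (adjusted p = 0.461), miR-451 (adjusted p = 0.0529) and miR-19b. The first day only ended those of miR-27a (adjusted p = 0.185), miR-101a and miR-19b (adjusted p = 0.263 for both), miR-338 (adjusted p = 0.482) and miR-451 (adjusted p = 0.0737), and the day block those of miR-27a, miR-101a, miR-338, miR-19b and miR-144.

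On Agilent at 36 hpf the count of 1 became 0 with the 75th percentile over all miRNA probes, quantile normalization, normexp background, the mean of the probes of a miRNA, trend and robust variance, only the compared groups and the second slide only. At 60 hpf the count of 6 became 3 with the 75th percentile over all miRNA probes (3 higher, 0 lower), quantile normalization (2 higher, 1 lower), no filter on dim probes (2 higher, 1 lower) and the second slide only (3 higher, 0 lower), and 2 with normexp background (1 higher, 1 lower) and only the compared groups (2 higher, 0 lower). The share of higher calls moved from 83.3% to 100%, 66.7%, 66.7% and 50% with the 75th percentile, quantile normalization, no filter and normexp. Over both stages the count of 5 became 3 with the 75th percentile over all miRNA probes, 2 with quantile normalization, the slide block and the second slide only, 1 with normexp background and 0 with no filter on dim probes. The 2 interactions became 0 with the 75th percentile over all miRNA probes, the mean of the probes of a miRNA and the second slide only, and 1 with quantile normalization, normexp background and trend and robust variance. The fits of the second slide and of the compared groups have fewer arrays. Where Agilent counts were 0 by limma, 3 to 15 miRNAs were at an unadjusted p under 0.05.

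On Exiqon median centring gave 0 calls at 36 hpf, at 60 hpf, over both stages and in the interaction by limma, with 5, 17, 8 and 13 miRNAs at an unadjusted p under 0.05; it raised the median standard error from 0.0451 to 0.105, while the changes of miR-23a (0.34), miR-24 (0.26) and miR-27c (0.37) at 60 hpf were not smaller by 0.01 or more. The sample channel alone, quantile normalized, gave 0 calls at 36 hpf, 4 at 60 hpf (4 higher, 0 lower), 2 over both stages and 0 interactions, with a median standard error of 0.0693. Its share of higher calls was 100% at 60 hpf, against 78.6%, and 100% over both stages, against 64.3%, where the value table gave 50%. Only the compared groups gave 3 calls at 36 hpf (2 higher, 1 lower) and 9 at 60 hpf (8 higher, 1 lower). Over both stages the day block gave 9 calls (8 higher, 1 lower) and the first day only 9 (7 higher, 2 lower), and the filter above negative controls gave 5 interactions. Median centring moved the median interaction from 0.015 to 0.135.

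The cross-platform correlation with no filter on dim probes was 0.30 at 60 hpf, 0.37 over both stages and 0.81 between stages, and with quantile and median centring 0.43 over both stages and 0.82 between stages.

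The labels do not say what the replicate numbers share, and not every pair of same-numbered samples deviated together, so the samples were not taken as paired. On Agilent the deviations from the group means correlated from -0.54 to 0.61 (11 of 18 pairs over 0.1), with a mean of 0.14 against -0.059 for other samples, and 8 of 12 samples correlated best with their own number, a hint that some structure follows the numbers; replicate 1 of each group shared a slide. On Exiqon they correlated from -0.29 to 0.26 (3 of 18 over 0.1), with a mean of -0.0078 against 0.0035, and for 2 of 12 samples best with their own number. With the replicate block, Agilent gave 1 call at 36 hpf, 6 at 60 hpf, 1 over both stages, 0 interactions and 105 between stages, and Exiqon gave 1, 12, 15 and 3, with a count between stages within 1.5 times.

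Some changes between stages turned sign with the scaling. On Agilent the 75th percentile over all miRNA probes gave miR-1 -0.013, miR-153a -0.088, miR-16b -0.036, miR-16c -0.16, miR-184 -0.27, miR-23a -0.076, miR-23b -0.053, miR-24 -0.25, miR-26a -0.13, miR-27c -0.099, miR-30b -0.020 and miR-30d -0.066. Quantile normalization gave miR-101a -0.055, miR-139 -0.36, miR-141 -0.15, miR-144 -0.17, miR-16b -0.094, miR-16c -0.096, miR-184 -0.37, miR-206 0.089, miR-23a -0.21, miR-23b -0.11, miR-24 -0.40, miR-26a -0.12, miR-27c -0.47, miR-30b -0.10 and miR-30d -0.26. Over the second slide only miR-184 was at -0.0076. On Exiqon median centring gave miR-130b 0.29, miR-133c 0.086, miR-141 0.29, miR-142b-5p -0.027, miR-153b 0.15, miR-17a 0.24, miR-18c 0.23, miR-196a 0.057, miR-196b 0.045, miR-19a 0.22, miR-19b 0.32, miR-19d 0.32, miR-200a 0.27, miR-200b 0.34, miR-203b* 0.056, miR-206 0.16, miR-20a 0.30, miR-20b 0.19, miR-222 0.29, miR-301c 0.25, miR-30a 0.075, miR-363 0.25, miR-429 0.20, miR-739 0.0049 and miR-92b 0.075. The sample channel alone gave miR-126 -0.17, miR-133a -0.31, miR-16a -0.17, miR-16b -0.055, miR-23b -0.048 and miR-30b -0.033, and the value table miR-126 -0.0096 and miR-146b -0.044. The same settings moved the median of all miRNAs: on Agilent from 0.10 to -0.18 with the 75th percentile over all miRNA probes and -0.12 with quantile normalization, and on Exiqon from 0.12 to 0.32 with median centring and 0.051 with the sample channel alone.

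Of the treatment effects that turned sign, 2 had passed, both on Exiqon; the largest of the others were 0.29 for miR-101a on Agilent at 60 hpf and 0.34 for miR-146b on Exiqon at 36 hpf. On Agilent at 60 hpf normexp gave miR-101a -0.013, miR-144 -0.089 and miR-17a* -0.24, quantile normalization miR-144 -0.043 and miR-17a* -0.0066, the second slide only miR-17a* -0.0036 and the mean of the probes of a miRNA, of which 1 was saturated, miR-19b -0.025, and over both stages normexp gave miR-144 -0.024. On Exiqon at 36 hpf median centring gave miR-181a* -0.0029, miR-23a -0.074, miR-23b -0.079, miR-24 -0.079, miR-27b -0.017, miR-27d -0.049 and miR-27e -0.011, the sample channel alone miR-144 0.043 and miR-181a* -0.051, the value table miR-146b -0.038 and miR-181a* -0.050, the day block miR-181a* -0.018 and miR-451 0.0067 and the first day only miR-451 0.00094. The sample channel alone turned the 2 that had passed, both falls, with miR-19b 0.075 at 60 hpf and miR-203b 0.056 over both stages. The first day only gave an interaction of miR-181a* -0.031.

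With each array left out in turn, Agilent gave 0 to 3 calls at 36 hpf (3 without replicate 1 of 36 hpf DMSO, 0 without replicate 2 of DMSO or replicate 1 or 3 of TCDD), 3 to 5 at 60 hpf (3 without replicate 3 of 60 hpf TCDD), 1 to 5 over both stages (3 without replicate 1 or 3 of 36 hpf DMSO or replicate 1 of 60 hpf TCDD, 5 without replicate 2 of 60 hpf TCDD, 1 without any other), 0 to 2 interactions (2 without replicate 1 of 60 hpf TCDD, 1 without replicate 3 of 36 hpf DMSO, 0 without any other) and 99 to 110 between stages. Exiqon gave 1 to 1 at 36 hpf, 11 to 48 at 60 hpf (48 without replicate 2 of 60 hpf TCDD), 7 to 25 over both stages (7 without replicate 1 of 36 hpf DMSO, 8 without replicate 2 of 36 hpf DMSO or TCDD, 9 without replicate 1 or 3 of 36 hpf TCDD or replicate 3 of 60 hpf DMSO, 25 without replicate 2 of 60 hpf TCDD), and 0 to 13 interactions (0 without replicate 3 of 36 hpf DMSO, 1 without replicate 1 of 36 hpf DMSO, 36 hpf TCDD or 60 hpf DMSO, 6 and 13 without replicate 1 and 2 of 60 hpf TCDD). Replicate 2 is the only 60 hpf TCDD array of the first image analysis day, so without it treatment and day cannot be told apart at 60 hpf. At 60 hpf the Agilent calls of miR-23a, miR-24 and miR-27c held without any array; that of miR-451 ended without replicate 1 (adjusted p = 0.09) or 3 (adjusted p = 0.0658) of DMSO or replicate 2 (adjusted p = 0.0506) or 3 (adjusted p = 0.111) of TCDD, that of miR-122 without replicate 1 or 3 of TCDD (adjusted p = 0.195 and 0.192), and that of miR-23b without any but replicate 2 of TCDD (highest adjusted p = 0.195). On Exiqon those of miR-23a, miR-23b, miR-24, miR-27b, miR-27c, miR-27d, miR-27e, miR-17a*, miR-101a and miR-451 held without any array, and that of miR-144 ended without replicate 3 of DMSO (adjusted p = 0.0583) or of TCDD (adjusted p = 0.0575). Those of miR-19b, miR-27a and miR-338 ended on leaving out any one of 4, 3 and 4 of the 6 arrays. Ranges that crossed 0 were, on Agilent, miR-144 -0.034 to 0.14 at 36 hpf, miR-27c -0.0039 to 0.19 at 36 hpf, miR-101a -0.047 to 0.51 at 60 hpf, miR-144 -0.12 to 0.15 at 60 hpf, miR-17a* -0.017 to 0.035 at 60 hpf, miR-19b -0.073 to 0.12 at 60 hpf (on a probe saturated on 5 of the 6 arrays, so its sign decides nothing), miR-144 -0.033 to 0.11 over both stages and miR-223 -0.11 to 0.017 between stages. On Exiqon at 36 hpf they were miR-181a* -0.024 to 0.057, miR-27a -0.041 to 0.0013, miR-27d -0.0062 to 0.063 and miR-451 -0.044 to 0.00098. At 60 hpf the lowest Agilent values of miR-144 and miR-101a came without replicate 2 of DMSO. On that array 191 probes were detected, against up to 277 on other arrays, and the lowest detected signal was 1065. Whether this accounts for those values was not tested. Of 1992 comparisons for single miRNAs with an array left out, 1755 kept direction and side of the threshold, 207 lost the call, 12 gained it and 18 changed sign.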

Other observations

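The tests in this part were chosen after the results were seen.

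The change between stages was also fitted in the TCDD groups, whose Exiqon arrays of both ages were of the same scan. It correlated with that in DMSO embryos at r = 0.99 on Agilent (Spearman's rho = 0.97) and r = 0.98 on Exiqon (Spearman's rho = 0.94), across miRNAs. On Agilent 109 miRNAs passed and 99 passed in both treatments, all 99 with the same sign; on Exiqon 108 rose and 38 fell past the threshold, and all that passed in both treatments had the same sign.

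The treatment effects at 36 and 60 hpf, which share no arrays, correlated at r = -0.02 on Agilent (Spearman's rho = -0.15) and r = 0.24 on Exiqon (Spearman's rho = 0.25). On Exiqon the later image analysis day held only TCDD arrays, of both stages, so a shift of that day could enter both effects. Whether it accounts for the Exiqon correlation was not tested. Only miR-17a* on Exiqon passed at both stages. Deviations from the group mean of samples with the same group and number on the platforms correlated at a mean r of 0.01, against -0.01 for other samples of the group.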
